A study of Arabidopsis thaliana with 12 samples.

How the data were processed

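Leaf 3 of 35S::gai-GR seedlings was profiled on 12 Affymetrix ATH1 arrays, 3 for each of 4 groups: mock and DEX at 1 h and at 4 h. Per the labels, the seedlings were 9 days old and received 5 µM dexamethasone or DMSO. Per the series description, leaves of 128 plants were dissected, without a statement whether per sample or in all, and the samples came from independent experiments. The deposited values are log2 expression per probe set after RMA by the authors, per the submitters' processing notes; RMA removes background, normalizes between arrays and summarizes the probes of a set. The version, the software and the probe set definition are not stated in the sources used here. The values lie on a log2 scale, from 4.43 to 14.1. No pair of arrays was identical (0 pairs), and 0 columns belonged to other series.

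The table holds 21492 probe sets. The 64 AFFX control sets were kept out of the tests and used for quality measures, and the other 21428, 1 per locus, were tested without a filter on level. Of these, 21231 are named in the reference (TAIR10.1, used for names and never for coordinates), 8728 with a symbol of their own, and 21120 stand for exactly 1 gene. A further property of the table is that 221 loci share all values with another locus, which leaves 21313 distinct profiles; such loci were not named. Arrays give no count of molecules, so precision rests on 3 arrays per group.

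Groups were compared with limma 3.58.1 in R 4.3.3: 1 mean per group, all 12 arrays sharing the spread (8 residual and 5.85 prior degrees of freedom), two-sided tests and Benjamini-Hochberg adjustment over 21428 loci, called at an adjusted p under 0.05. The comparisons were DEX against mock at 1 h and at 4 h, the difference of these responses, and mock 4 h against mock 1 h. Calls shared by both times were counted per direction and tested with Fisher's exact test, one-sided. No mock array serves both times.

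The 24 gene lists hold 341 members, of which 301 were measured; the symbol given names the locus for 333, and 8 are known by locus only. They cover gibberellin biosynthesis and receptors, gibberellin catabolism, DELLA genes and regulators, other early DELLA targets of seedlings, expansins, xyloglucan enzymes, growth bHLH and shade genes, the mitotic cycle, DNA replication, CDK inhibitors and endoreduplication, leaf growth regulators, jasmonate, auxin, brassinosteroid, ethylene, cytokinin, abscisic acid and cold, touch and wounding, the circadian clock and photosynthesis, with shoot meristem, root, trichome and stomatal lineage as markers of other tissue. Lists were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 24. An estimated correlation, fry and camera on ranks were alternatives. Members were also adjusted over the list alone.

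These groups, tests, lists and alternatives, and the rule for named genes, were chosen before the data were examined. The rule takes the 12 largest rises and 12 largest falls at each time among loci of exactly 1 gene that passed without overlap, GAI and RGA, up to 4 members of each list with the smallest p at 4 h and up to 2 at 1 h, and 5 per direction for the other 2 comparisons. Genes added after their values were seen are PIN4, GID1B, BHLH137, TRY and GH3.6, which complete lists where 5 or fewer members passed in a direction. The loci called at 1 h alone and the anthocyanin regulators of the closing section were also picked after their values were seen. At most 163 genes are named.

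The alternatives were a replicate block, only the arrays of 1 comparison, loci with a mean log2 of at least 5, the brighter probe sets, renewed quantile normalization, centring on the median, a variance trend with robust fitting, array weights, loci of exactly 1 gene, a stricter adjusted p of 0.01, a 2-fold minimum, and leaving out each array and each replicate number. Added after the data were seen were the lists without mock 4 h replicate 2, identical loci kept once, and centring combined with leaving out that array. Single values were compared by exact permutation tests over 924 splits of the 12 arrays. Figures were drawn with matplotlib 3.10.9.

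The fits were tested on simulated data with 21428 genes, some changed by known amounts. For the 1 h comparison, 31 of 67 genes changed by log2 0.5 were recovered, 63 of 67 changed by 1 and 66 of 66 changed by 2, with 14 false among 179 calls. For the 4 h comparison the numbers were 27, 62 and 66, with 5 false among 166 calls. A replication list shifted by -0.4 was found at both times, and 0 other lists passed camera. Of the calls at 1 h and 4 h, 5 and 6 were members of that list. Simulated genes were drawn independently, without correlation between genes and without an array that stands apart. The simulation therefore cannot show how often camera passes a list falsely in the real arrays. Each simulated gene had 1 SD for all groups, and both runs changed the same number of genes. Differences between the runs thus come from the draw and do not compare the times.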

Results

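The measurements are mRNA levels in the third leaf of Arabidopsis seedlings, 9 days after stratification, on Affymetrix ATH1 arrays. The plants, of the Col-0 background, express gai-GR under a constitutive viral promoter. The gai protein is a DELLA repressor of growth that resists gibberellin-triggered breakdown, and its fusion to the glucocorticoid receptor domain keeps it out of the nucleus until dexamethasone is given. Plants stayed on 5 µM dexamethasone (DEX) or on solvent alone (mock) for 1 h or 4 h. Each of the 4 groups has 3 arrays, each from an independent experiment, so 12 arrays in all. The number of arrays, not a read depth, limits the precision. The standard error of a log2 fold change of DEX against mock had a median of 0.12 at both times, since all groups share 1 estimate of the spread. Plants without the transgene under dexamethasone are not analysed here, so each comparison measures dexamethasone and gai-GR together. Genes are named by their symbol and locus. The table gives no coordinates and none are stated.

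GAI (AT1G14920), the gene from which the transgene derives, lay near the top of the scale in every group. Its log2 level was 12.86 ± 0.05 in mock and 12.85 ± 0.04 in DEX at 1 h, and 12.94 ± 0.04 and 12.94 ± 0.03 at 4 h (SD, n = 3 each). Its log2 fold change was -0.01 (SE 0.08) at 1 h, with a limma adjusted p of 1, and 0.00 at 4 h, with an adjusted p of 0.99. The probe set can read the transgene as well as the plant's own gene, and the hormone releases an existing protein, so GAI's level says nothing about activation. RGA (AT2G01570), the closest DELLA relative, fell by 0.52 (SE 0.10, adjusted p = 0.026) at 1 h and by 0.98 (adjusted p = 1.8e-05) at 4 h on the log2 scale. The 1 h call ended without any of 5 single arrays of that time, with adjusted p up to 0.169 for mock 1 h replicate 2.

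**Figure D1:**
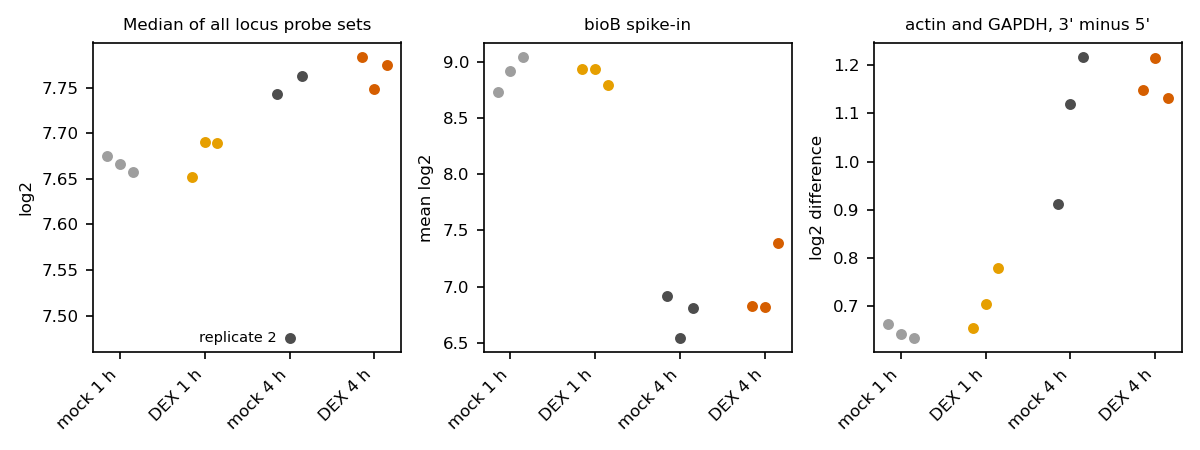
Quality measures of the 12 arrays by group: the median log2 level of all loci, the log2 signal of the bioB spike-in, and the 3' minus 5' log2 signal of the actin and GAPDH control probe sets. Mock 4 h replicate 2 has the lowest median, 7.48, and every 4 h array has a lower bioB signal and a higher 3' minus 5' signal than every 1 h array.

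Array medians ran from 7.48 to 7.78 on the log2 scale. Mock 4 h replicate 2 was the lowest, and the other 4 h arrays had medians of 7.74 to 7.78. Its correlations with the other mock 4 h arrays, across genes, were 0.987 and 0.988, while those arrays correlated with each other at 0.995. Genes are not independent replicates, so these coefficients are descriptions.

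After 1 h on dexamethasone, the genes that rose most encode enzymes that make gibberellin. GA20OX2 (AT5G51810) and GA20OX1 (AT4G25420), oxidases of the late pathway, rose 20.6-fold (log2 4.37, SE 0.17) and 14.9-fold (log2 3.89, SE 0.16). GA3OX1 (AT1G15550), which forms the bioactive hormone, rose 9.01-fold (log2 3.17, SE 0.25), and XERICO (AT2G04240), a RING-type protein that promotes abscisic acid accumulation, 6.25-fold (log2 2.64, SE 0.11), with 3 arrays per group. Further large rises were those of AT2G40435 (log2 2.67), the SAUR-family gene SAUR9 (AT4G36110, 2.60), the transcription factor WRKY18 (AT4G31800, 2.46), TRM13 (AT2G45900, 2.25), the guard-cell potassium channel KAT2 (AT4G18290, 1.97), AT2G39980 (1.93) and ESE3 (AT5G25190, 1.91). BAS1 (AT2G26710), a cytochrome P450 that inactivates brassinosteroids, rose by 1.80 (SE 0.12).

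Falls at 1 h were smaller. AT2G21210, named SAUR6 among its synonyms, fell by 1.11 (SE 0.16, adjusted p = 0.0021) on the log2 scale and is the 1 gene with a fall of at least 2-fold. AT1G78170 fell by 0.75, AT1G23390 by 0.69 and COL2 (AT3G02380), a CONSTANS-like zinc finger gene, by 0.59 (SE 0.09). The growth-regulating factor GRF6 (AT2G06200) fell by 0.77, TCP17 (AT5G08070) by 0.67, AT4G34760 (SAUR50) by 0.64, the transporter gene ABCG19 (AT3G55130) by 0.58, AT1G32690 by 0.57, the homeobox gene HB5 (AT5G65310) by 0.55 and the organ boundary gene CUC3 (AT1G76420) by at least 0.54, since its DEX level of 5.65 lay near background.

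By limma with Benjamini-Hochberg adjustment, 153 of 21428 loci changed at 1 h: 135 rose and 18 fell. Of these, 54 rose and 1 fell at least 2-fold, and 1068 loci had an unadjusted p under 0.05. The count was 90 without mock 1 h replicate 2, 97 without mock 1 h replicate 3 and 263 without mock 4 h replicate 2, which shares in the estimate of the spread. Of 37 named calls at 1 h, 12 ended when a single array was left out: GRF6, TCP17, AT4G34760, ABCG19, AT1G32690, HB5, CUC3, RGA, AT1G56650, CRF6, IAA3 and BHLH137, with adjusted p up to 0.243, for AT1G32690 without mock 1 h replicate 2.

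Among 24 lists of genes fixed in advance, the list of gibberellin biosynthesis enzymes and receptors rose at 1 h. Of its 13 measured members, 5 rose, none fell and 8 did not pass; adjusted over the list alone, 6 rose and 0 fell. The 5 are GA20OX1, GA20OX2, GA3OX1, GA20OX3 (AT5G07200, log2 1.82, SE 0.17) and the gibberellin receptor gene GID1B (AT3G63010, log2 1.52, SE 0.18, adjusted p = 0.00049). The list's median log2 fold change was 0.24 and its mean 1.21. Other early DELLA targets, known from seedlings, rose as a list, with a median of 0.89: 5 of 8 members rose, 3 did not pass, and all 8 rose when adjusted over the list alone. They are XERICO, SCL3 (AT1G50420, a GRAS protein that acts in gibberellin signalling; log2 1.58), LBD40 (AT1G67100), AT3G11280 (1.02) and BHLH137 (AT5G50915, 0.77). The camera test gave adjusted p = 3.78e-22 for the gibberellin list and 1.17e-29 for the early targets. Both calls hold with an estimated correlation, at adjusted p = 0.00865 and 0.00155. GID1B and BHLH137 were picked after their values were seen.

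The other 22 lists did not pass at 1 h. Their smallest adjusted p was 0.419, and their medians ran from -0.12 to 0.09. Single members changed in some of them: XTH15 (AT4G14130, log2 1.19), a wall-modifying enzyme gene; IAA3 (AT1G04240, 0.61), an auxin repressor gene; ERF2 (AT5G47220, 0.89), of the ethylene list; CRF6 (AT3G61630, 0.75), of the cytokinin list; and BAS1, of the brassinosteroid list. RGA, GRF6 and CUC3 were the 1 fall in their lists. IAA3, CRF6, RGA, GRF6 and CUC3 lost their calls without a single array, with adjusted p up to 0.171 for IAA3 without mock 1 h replicate 3. Adjusted over the list alone, 1 rose and 1 fell in each of the DELLA, growth bHLH and cytokinin lists, 2 rose among brassinosteroid genes, and 1 rose among the jasmonate genes. In the mitotic list 0 of 21 passed by limma (1 at an unadjusted p under 0.05), and in the replication list 0 of 16 (0 at that level). Median, mean and test differed in sign for 4 of these lists, the xyloglucan, brassinosteroid, touch and photosynthesis genes.

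At 4 h the gibberellin genes again led the rises, now joined by a regulator and an enzyme of anthocyanin synthesis. GA20OX2 was 40.5-fold above mock (log2 5.34, SE 0.17, adjusted p = 4e-10), GA20OX3 at least 27.4-fold (log2 4.78, SE 0.17), GA20OX1 17.6-fold and GA3OX1 17.5-fold, with 3 arrays per group. AT1G56650, the MYB75 gene also called PAP1, an activator of anthocyanin synthesis, rose 14.8-fold (log2 3.89, SE 0.25), and DFR (AT5G42800), an enzyme of that pathway, 10.4-fold (log2 3.37, SE 0.29). AT5G65040 (log2 3.33), the receptor-like kinase gene CRK12 (AT4G23200, 3.27), XERICO (3.18), SAUR9 (3.17), the purine permease gene PUP1 (AT1G28230, 3.04) and MEE3 (AT2G21650, 3.01) complete the 12 largest rises. The mock levels of GA20OX3 and SAUR9 were 5.61 and 5.46, under the lower quartile of every array (5.79 or more) and near background, so their changes at both times are lower bounds.

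The deepest fall at 4 h was that of KLU (AT1G13710), a cytochrome P450 that promotes organ growth, which was 4.22-fold lower (log2 -2.08, SE 0.20, adjusted p = 7.8e-06). DIR1 (AT5G48485), a lipid transfer protein of systemic resistance, was 3.21-fold lower, and BXL1 (AT5G49360), a wall beta-xylosidase, 3.16-fold lower. BXL2 (AT1G02640) fell by 1.44, the light-harvesting gene LHCB2.3 (AT3G27690) by 1.39, the expansin gene EXPA3 (AT2G37640) by 1.37 and KNAT1 (AT4G08150), a homeobox gene of the shoot meristem, by 1.33. AT1G23390 fell by 1.52, AT1G06080 (ADS1, a fatty acid desaturase) by 1.42, AT2G03550 by 1.36, AT2G20670 by 1.35 and PAR1 (AT2G42870) by 1.33.

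By limma, 1693 of 21428 loci changed at 4 h, 1146 up and 547 down, or 67.7% up; 274 rose and 62 fell at least 2-fold. The unadjusted p was under 0.05 for 4479 loci. The direction split moved with the scaling and with 1 array. Renewed quantile normalization gave 49.6% up, centring each array on its median 40.0%, and leaving out mock 4 h replicate 2 49.9%, with 1519, 1402 and 1446 of the 1693 calls kept. Centring moved the median log2 fold change of all loci from 0.02 to -0.09.

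**Figure D2:**
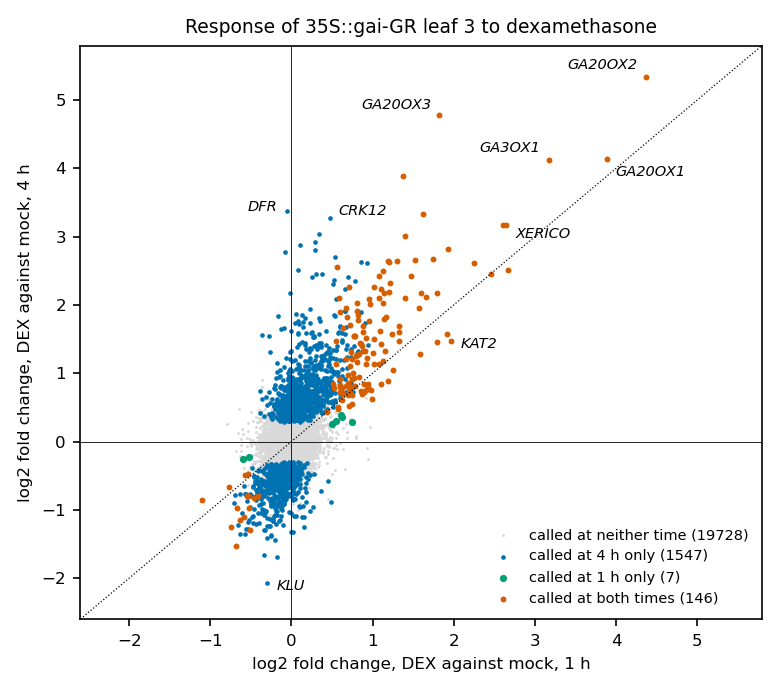
Each point is a locus, with its log2 fold change under dexamethasone at 1 h on the horizontal and at 4 h on the vertical axis, coloured by the time or times at which it passed; the dotted line marks equal change. The 146 loci that passed at both times lie on the same side of 0 at both, and GA20OX2 reaches 4.37 and 5.34.

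**Figure D3:**
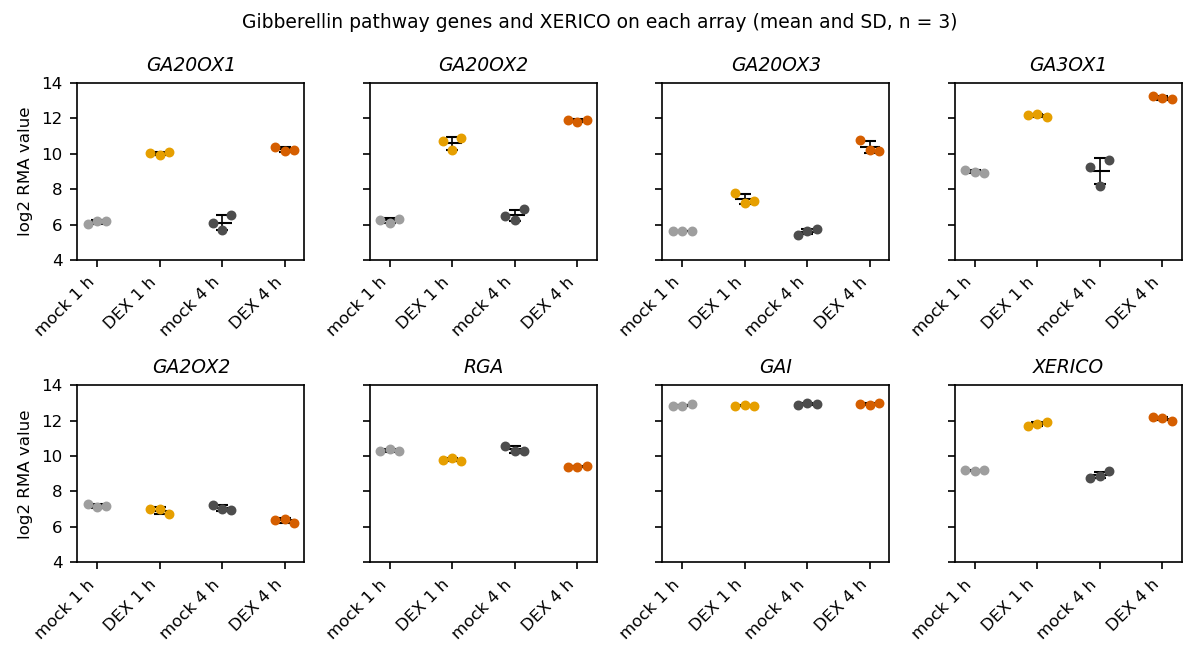
Log2 level on each array of gibberellin pathway genes and XERICO, by group, with the mean and SD of 3 arrays. GA20OX2, GA20OX1, GA20OX3, GA3OX1 and XERICO are higher in DEX at both times, RGA is lower, and GAI stays between 12.85 and 12.94 on average in all 4 groups.

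By camera the DNA replication, leaf growth and growth bHLH lists passed downward at 4 h (adjusted p = 8.83e-17, 9.98e-07 and 0.00824). These calls are lost with an estimated correlation, at adjusted p = 0.0850, 0.179 and 0.218. In the DNA replication list 11 of 16 members fell, none rose and 5 did not pass (15 fell adjusted over the list alone), and the median was -0.56. The licensing factor gene CDT1A (AT2G31270) fell by 0.83 (SE 0.11), the S-phase cyclin gene CYCA3;1 (AT5G43080) by 0.82 (SE 0.10), the polymerase clamp gene PCNA1 (AT1G07370) by 0.69 (SE 0.09) and TSO2 (AT3G27060), a ribonucleotide reductase subunit, by 0.56 (SE 0.08), n = 3 per group. Among leaf growth regulators 7 of 19 fell, none rose and 12 did not pass (11 fell adjusted over the list alone; median -0.34), led by KLU, GRF5 (AT3G13960, -0.96, SE 0.10) and its partner coactivator GIF1 (AT5G28640, -0.80, SE 0.12). In the growth bHLH and shade list 2 of 11 fell and 9 did not pass; the 2 are PAR1 and HBI1 (AT2G18300, -1.05); PAR1 restrains and HBI1 promotes elongation (adjusted over the list alone, 2 fell; median -0.15).

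The mitotic list did not pass at 4 h: 0 of 21 members by limma, 1 at an unadjusted p under 0.05, and 0 adjusted over the list alone. Its median was -0.01, and -0.08 without mock 4 h replicate 2, its mean 0.01 and its adjusted p 0.755. The list of CDK inhibitors and endoreduplication genes did not pass either (median -0.05, and -0.12 without mock 4 h replicate 2; adjusted p = 0.864). In it KRP1 (AT2G23430), a CDK inhibitor, rose by 0.60, and 12 of 13 did not pass; adjusted over the list alone, 2 rose and 1 fell.

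Gibberellin biosynthesis and receptors rose at 4 h in 10 of 13 members, with none lower and 3 not passing (11 rose adjusted over the list alone; median 0.90). GID1B reached log2 2.66 (SE 0.18). All 8 early DELLA targets rose, 8 also adjusted over the list alone, with a median of 1.77 and LBD40 at 2.65, AT3G11280 at 2.27 and SCL3 at 1.96. The camera adjusted p was 8.83e-17 for the gibberellin list and 2.33e-19 for the targets, and these calls hold with an estimated correlation, at adjusted p = 0.0217 and 0.00693. Gibberellin catabolism fell as a list (median -0.15, adjusted p = 0.0386), through 1 of 7 members, GA2OX2 (AT1G30040, -0.70, SE 0.12), an oxidase that inactivates the hormone; 1 also adjusted over the list alone. That call is lost with an estimated correlation, at adjusted p = 0.173, and without mock 4 h replicate 2, at 0.266. The median level of the catabolism list was 5.88, little above background, so falls of its members could be hidden.

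**Figure D4:**
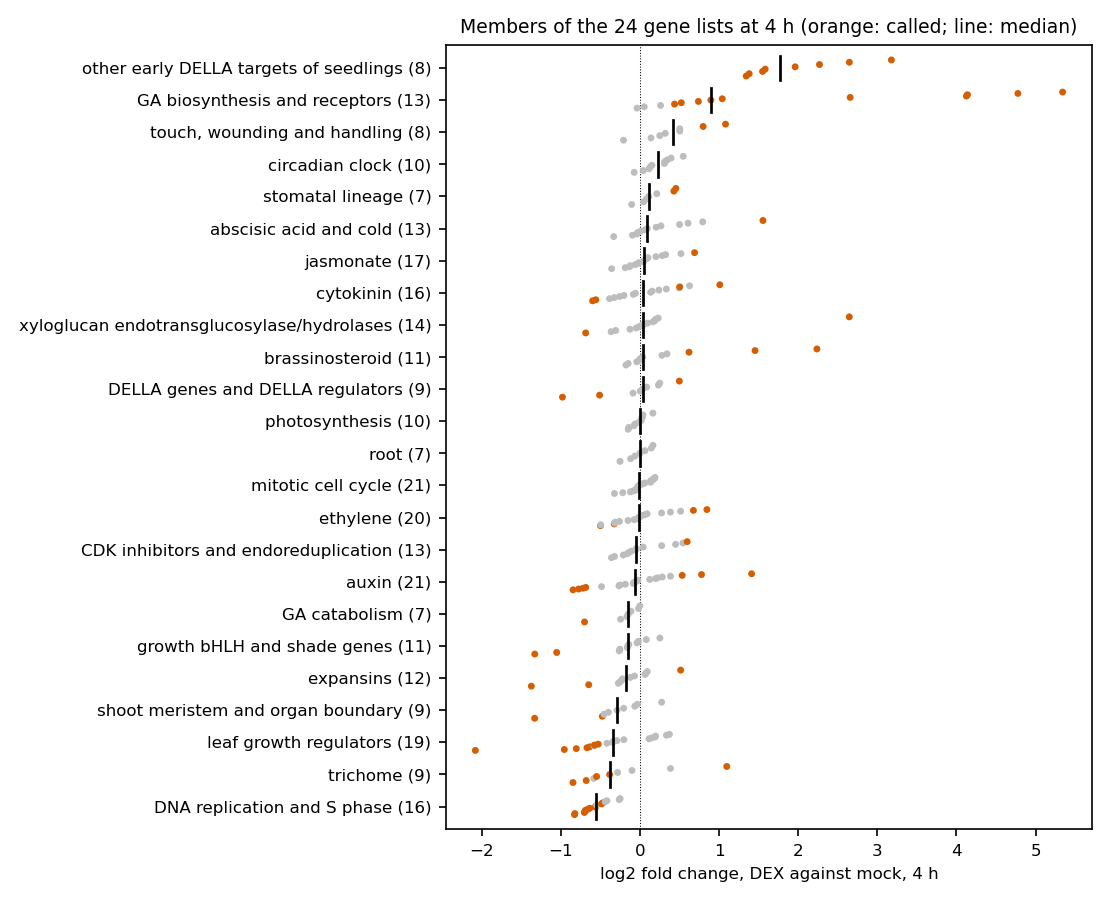
Log2 fold change under dexamethasone at 4 h of each measured member of the 24 gene lists; orange points are genes that passed and the line is the list's median. The early DELLA targets have a median of 1.77, the gibberellin biosynthesis and receptor genes 0.90, DNA replication genes -0.56 and mitotic genes -0.01.

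Of the brassinosteroid genes, 3 of 11 rose at 4 h, none fell and 8 did not pass (4 rose adjusted over the list alone). They act in opposite directions: BR6OX2 (AT3G30180, log2 2.24, SE 0.15) and DWF4 (AT3G50660, 0.62) make the hormone and BAS1 (1.45) inactivates it. The list passed upward, with a median of 0.04, a mean of 0.42 and adjusted p = 0.0301. The median was -0.07 when arrays were centred and 0.01 without mock 4 h replicate 2, and adjusted p = 0.461 with an estimated correlation. Expansins passed downward (median -0.17, adjusted p = 0.0301). EXPA3 and EXPA6 (AT2G28950, -0.65) fell, EXPA10 (AT1G26770) rose by 0.51, and 9 of 12 did not pass (1 rose and 3 fell adjusted over the list alone); adjusted p = 0.490 with an estimated correlation. Without mock 4 h replicate 2 the brassinosteroid call is lost, at 0.0677, and the expansin median is -0.28. DWF4 lost its call without DEX 4 h replicate 2, at 0.0501, and EXPA10 without DEX 4 h replicate 3, at 0.0553.

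Lists of tissue that a dissected leaf could carry along were read the same way. Shoot meristem and organ boundary genes fell at 4 h (median -0.29, adjusted p = 0.00137; 0.0925 with an estimated correlation). KNAT1 and CUC3 (-0.47, a lower bound of its fall, since DEX at 5.36 is near background) passed, and 7 of 9 did not (4 fell adjusted over the list alone). The median level of this list was 5.96, little above background, so falls of its members could be hidden. Trichome genes passed downward (median -0.38, adjusted p = 0.0450): GL1 (AT3G27920, -0.85), GIS (AT3G58070, -0.68), ZFP8 (AT2G41940, -0.55) and TRY (AT5G53200, -0.38) fell, TTG2 (AT2G37260, log2 1.10, SE 0.14) rose and 4 of 9 did not pass (2 rose and 4 fell adjusted over the list alone). TRY is known as a repressor of trichome fate, the other 3 that fell as promoters. Adjusted p = 0.461 with an estimated correlation, 0.0517 without mock 4 h replicate 2 and 0.118 when arrays were centred. GIS, ZFP8 and TRY lost their calls without a single array, with adjusted p up to 0.137 for TRY without DEX 4 h replicate 2; TRY was picked after its value was seen.

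Root, stomatal and photosynthesis genes did not pass as lists at 4 h. Root genes had a median of -0.00 (adjusted p = 0.727) and photosynthesis genes of 0.00 (0.534), which were -0.01 and -0.03 without mock 4 h replicate 2, with 0 of 7 and 0 of 10 passing by limma, 0 at an unadjusted p under 0.05, and 0 adjusted over the list alone. The median level of the root list was 6.06, little above background, so falls of its members could be hidden. That of the photosynthesis list, with 10 of 18 members measured, was 13.4, near the highest value of 14.1. Changes of its members could be compressed there. Of 7 stomatal lineage genes (median 0.11, and 0.06 without mock 4 h replicate 2; adjusted p = 0.199), TMM (AT1G80080, 0.45) and EPF2 (AT1G34245, 0.43) rose and 5 did not pass; 2 rose adjusted over the list alone. Without a single array TMM reached an adjusted p of up to 0.0714 (DEX 4 h replicate 3) and EPF2 of up to 0.137 (DEX 4 h replicate 2).

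Hormone and stress lists beyond these did not pass at 4 h. Auxin genes moved both ways, with 3 of 21 up, 4 down and 14 not passing (4 and 5 adjusted over the list alone; median -0.06, and -0.17 without mock 4 h replicate 2; adjusted p = 0.198). IAA17 (AT1G04250, log2 1.41), PIN3 (AT1G70940, 0.53) and PIN4 (AT2G01420, 0.78, and 0.46 without mock 4 h replicate 2) rose; IAA16 (AT3G04730, -0.84), GH3.5 (AT4G27260, -0.77) and GH3.6 (AT5G54510, -0.72) were among those that fell. Of 16 cytokinin genes, CRF6 (1.01) and ARR4 (AT1G10470, 0.50) rose, ARR15 (AT1G74890, -0.60) and CKX5 (AT1G75450, -0.56) fell and 12 did not pass (5 and 5 adjusted over the list alone; median 0.04, adjusted p = 0.898). Of 20 ethylene genes, 2 rose, among them ERF2 (0.85), 2 fell, ACO4 (AT1G05010, -0.50) and ACS11 (AT4G08040, -0.32, with DEX near background at 5.60), and 16 did not pass (3 and 3 adjusted over the list alone; median -0.01, and -0.07 without mock 4 h replicate 2; adjusted p = 0.568). PIN3, PIN4, ARR4, CKX5 and ACS11 lost their calls without a single array, with adjusted p up to 0.146 for CKX5 without DEX 4 h replicate 3. PIN4 and GH3.6 were picked after their values were seen.

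Of 13 abscisic acid and cold genes, RD29A (AT5G52310, log2 1.55, SE 0.22), a desiccation-induced gene, rose and 12 did not pass (3 rose adjusted over the list alone; median 0.09, and 0.17 without mock 4 h replicate 2; adjusted p = 0.199). Of 17 jasmonate genes, the repressor gene JAZ6 (AT1G72450, 0.69) rose and 16 did not pass (1 adjusted over the list alone; median 0.05, and -0.02 without that array; adjusted p = 0.664). Among 14 xyloglucan enzyme genes, XTH15 (2.65, SE 0.12) rose, XTH16 (AT3G23730, -0.68) fell and 12 did not pass (1 and 1 adjusted over the list alone; median 0.04, and 0.00 without that array; adjusted p = 0.880). Touch and wounding genes had a median of 0.41 and adjusted p = 0.0539. Of the 8, WRKY53 (AT4G23810, 0.80, with mock near background at 5.58) and ERF104 (AT5G61600, 1.08) rose and 6 did not pass (2 adjusted over the list alone). Clock genes had a median of 0.23 (0.13 without mock 4 h replicate 2; adjusted p = 0.115), with 0 of 10 passing by limma, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Of 9 DELLA genes and regulators, SLY1 (AT4G24210, 0.50), an F-box protein that targets DELLA proteins, rose, RGA and RGL1 (AT1G66350, -0.51) fell and 6 did not pass (1 and 2 adjusted over the list alone; median 0.03, and 0.01 without mock 4 h replicate 2; adjusted p = 0.514). ERF104 lost its call without DEX 4 h replicate 2, at 0.0587, and SLY1 without any of 5 single arrays, at up to 0.142 for that same array. Median, mean and test differed in sign for 6 lists, none of which passed: the DELLA, mitotic, CDK inhibitor, ethylene, cytokinin and photosynthesis genes.

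Of 24 lists, 10 passed by camera at 4 h, 3 upward and 7 downward, and 14 did not. With an estimated correlation 2 hold, and without mock 4 h replicate 2, 7 pass.

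Most genes that rose at 1 h, among them GA20OX2, GA3OX1 and XERICO, also rose at 4 h. Of the 135 that rose at 1 h, 130 rose again, where independent lists would share 7.22 (Fisher's exact test, one-sided, p = 9.26e-161). Of the 18 that fell, 16 fell again, against 0.459 (the same exact test, p = 3.82e-24). By limma 0 changed in opposite directions. No mock array serves both times, but both comparisons use the same estimate of each gene's spread. Genes are also not independent units, so the exact p-values are descriptions. Among the 130 shared rises the median log2 fold change was 0.91 at 1 h and 1.46 at 4 h. The 7 loci called at 1 h alone, chosen after their values were seen, were IAA3, COL2, AT3G16330, AT3G54000, RIC7 (AT4G28560), AT4G30470 and bHLH071 (AT5G46690); all had the same sign at 4 h, and the smallest adjusted p of their interaction was 0.295, so no loss of response was shown. The shared count was 146; it was 87 without mock 1 h replicate 2, 96 without mock 1 h replicate 3 and 235 without mock 4 h replicate 2.

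Some genes responded differently at 4 h than at 1 h. The difference of the 2 responses was largest for DFR, whose log2 fold change was 3.42 higher at 4 h (SE 0.41, adjusted p = 0.00066), GA20OX3 (2.95, adjusted p = 2.1e-05, inexact since its mock levels lie near background), UF3GT (AT5G54060, 2.85), CRK12 (2.79) and AT4G14090 (2.78). UF3GT is a glycosyltransferase of the anthocyanin pathway. The response was more negative at 4 h for KLU (-1.78, adjusted p = 0.0049), DIR1 (-1.50), LSH10 (AT2G42610, -1.41), CGA1 (AT4G26150, -1.37), a GATA factor of chloroplast development, and KNAT1 (-1.34), with 3 arrays in each of the 4 groups. By limma 274 loci passed this test, 207 higher and 67 lower at 4 h, or 75.5% higher; 110 and 22 differed at least 2-fold, and 2473 had an unadjusted p under 0.05. Renewed quantile normalization gave 57.4% higher and centring 57.7%. The count was 170, 170 and 175 without mock 1 h replicate 1, 2 and 3, 174 without DEX 1 h replicate 2 and 412 without mock 4 h replicate 2.

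Mock plants at 4 h differed most from mock plants at 1 h in genes that include clock, light-induced and cold-induced ones. AT1G56300 was 18.1-fold higher at 4 h (log2 4.18, SE 0.11), the dormancy-associated gene AT2G33830 (DRM2) log2 3.75 higher, the clock gene PRR5 (AT5G24470) 2.67 (SE 0.28), the cold-induced COR15B (AT2G42530) 2.27 and RbcX1 (AT4G04330), a Rubisco assembly factor, also 2.27 (a lower bound, with mock at 1 h near background at 5.62), n = 3 per group. The early light-induced genes ELIP1 (AT3G22840) and ELIP2 (AT4G14690) were lower by log2 -3.23 and -2.53, COL2 by -2.76, and the morning clock genes LHY (AT1G01060) and CCA1 (AT2G46830) by -2.87 and -2.40. By limma 1990 of 21428 loci differed, 781 up and 1209 down, 39.2% up; 79 and 56 by at least 2-fold, with 5240 at an unadjusted p under 0.05.

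Sampling time cannot be told apart from array processing in that comparison. The bioB spike-in, which no plant RNA contributes to, averaged 8.89 at 1 h and 6.88 at 4 h on the log2 scale (6 arrays each, exact permutation test, two-sided, p = 0.00216). The spike-ins bioC, bioD and cre did not follow it: they read higher at 4 h by 0.08, 0.34 and 0.15 (p = 0.686, 0.0325 and 0.0216 by the same exact permutation test). The actin and GAPDH 3' minus 5' signal averaged 0.680 and 1.12 (p = 0.00216 by that exact permutation test). Over the 7 control measures tested, the adjusted p is 0.00758 for bioB and for this signal, 0.0455 for bioD, 0.0379 for cre and 0.801 for bioC by exact permutation. It is 0.0303 for the mean of these hybridization spike-ins and 0.861 for the poly-A spike-ins by the same test. Only bioB and the 3' minus 5' signal separate the times without overlap. Whether the times were processed apart is not stated in the sources used here. Each time holds both treatments, so an additive offset common to all arrays of 1 time would cancel between its DEX and mock. Differences between arrays within a time need not cancel. The SD over 6 arrays was 0.037 at 1 h and 0.52 at 4 h for bioC, 0.056 and 0.40 for bioD, and 0.094 and 0.64 for the poly-A spike-ins. The mock count was 1013, 968 and 945 without mock 1 h replicate 1, 2 and 3; the share up was 49.8% after renewed quantile normalization and 60.0% without mock 4 h replicate 2.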

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

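The tests on array quality and chance splits were set before their results were seen, while the choice of the array, the anthocyanin lists and the cycling-cell comparison came afterwards, as did the list tests of the difference between times and the tests of a fall in mock plants, of a lower share of cycling cells and of the poly-A spike-ins.

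The response to dexamethasone differed between 4 h and 1 h by a test of the difference itself for 274 genes. It was higher at 4 h by log2 3.42 for DFR, 2.95 for GA20OX3 (inexact, since its mock levels lie near background), 2.85 for UF3GT, 2.79 for CRK12 and 2.78 for AT4G14090. It was lower for KLU at -1.78, DIR1 at -1.50, LSH10 at -1.41, CGA1 at -1.37 and KNAT1 at -1.34. Of the lists, gibberellin biosynthesis and receptors had a median difference of 0.55 (camera adjusted p = 5.51e-08) and the early DELLA targets of 0.92 (2.29e-10). DNA replication had -0.52 (3.46e-16), growth bHLH and shade genes -0.29 (0.000347), leaf growth regulators -0.21 (1.65e-06), auxin -0.14 (0.0467) and the shoot meristem -0.12 (0.0330). With an estimated correlation 0 of these 7 lists pass, and the smallest adjusted p is 0.0561, for the early targets. The list differences were not run without mock 4 h replicate 2. Without it the 4 h medians moved from -0.34 to -0.49 for leaf growth regulators, -0.06 to -0.17 for auxin and -0.29 to -0.21 for the shoot meristem. Of 100 draws of splits within each time, 10 gave as many genes, the real one included, and the highest other count was 736. All 10 keep the real grouping at 4 h, so the 4 h response stays in them and they do not test the difference between the responses; chance is left open for this count.

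The control probe sets, which take no part in the comparisons, differed between times. The bioB spike-in changed by log2 -2.01 from 1 h to 4 h, while bioC, bioD and cre changed by 0.08, 0.34 and 0.15, and the actin and GAPDH 3' minus 5' signal by 0.44.

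Mock 4 h replicate 2 stands apart from the other mock 4 h arrays, with a median of 7.48. Its 3' minus 5' signal of 1.12 lies inside the 0.633 to 1.22 of the other 11 arrays. That range spans both times, but the 4 h arrays alone ran from 0.912 to 1.22. Stronger RNA degradation than on the other 4 h arrays was therefore not seen by this measure, though a wide range leaves a smaller difference open. Its hybridization spike-ins averaged 9.91, below the lowest of the other 11 at 10.2, so a weaker hybridization is a candidate explanation. A shift of these spike-ins alone need not set an array apart. DEX 4 h replicate 3 read 10.9, above the other 4 h arrays, yet correlated with its group at 0.993 and 0.994. Labelling stays open, since these spike-ins enter already labelled. The poly-A ones, which report labelling, read 7.30 within a wide 6.06 to 7.83 of the others. The 6.06 is that of mock 4 h replicate 1. Another share of other tissue stays open: 0 of 5 marker lists lay outside their matched random lists, but those ranges were wide (-0.46 to -0.01 for trichome genes), and for that reason the reading was changed after the result from excluded to open. The design names no biological difference for this array, so none was tested.

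Anthocyanin genes were higher with dexamethasone at 4 h. Of 10 measured structural genes 9 rose, with a median of 2.34; the list was drawn up because its members led the rises, so its adjusted p of 0.0364 with an estimated correlation is no independent evidence. Without mock 4 h replicate 2 the median was 2.09, which argues against that array as the source. In mock plants 9 of the 10 fell between 1 h and 4 h (median -1.05). DEX at 4 h was above mock at 1 h by a median of 1.38, and by at least 1.06 for all but TT4, TT5 and F3H. For the genes at 1.06 or more this argues against a fall in mock plants alone, though time and array processing cannot be told apart there. TT4, TT5 and F3H stood at -0.01, -0.31 and 0.24, with mock changes of -1.62, -0.88 and -1.42. A fall in mock plants stays open for them. Activation through AT1G56650 may account for the rise of the list. That gene had risen by 1.37 at 1 h (a call lost without some single arrays, at adjusted p up to 0.107 for mock 1 h replicate 3). At 1 h 0 of the 10 passed by limma (0 at an unadjusted p under 0.05). Dexamethasone itself stays open without plants that lack the transgene.

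DNA replication genes fell at 4 h, by a median of -0.56 (95% bootstrap interval -0.69 to -0.47; list adjusted p = 0.0850 with an estimated correlation, so not passing there), and mitotic genes had a median of -0.01 (-0.034 to 0.13). The difference of -0.55 had p = 1e-05 in a permutation test across genes, the smallest that 1e+05 resamples can give, and genes are not independent replicates. An equal loss of cycling cells would lower both lists alike. The mitotic lower bound of -0.034, beside a replication median of -0.56, argues against an equal loss by 4 h. The intervals resample genes with the arrays held fixed, so they leave out the spread between arrays. Without mock 4 h replicate 2 the replication median was -0.70 and the mitotic one -0.08, which lies below the mitotic interval. The mitotic list's median level of 9.98 argues against genes too dim to show a fall. What lowered the replication genes stays open, as does a mitotic fall after 4 h. Histone genes do not decide it, since their list was drawn by symbol and not by expression in S phase. Of its 18 genes 0 passed by limma, with 5 at an unadjusted p under 0.05. Their median was -0.13, and -0.25 without mock 4 h replicate 2.

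Other splits of the arrays give a limited view of chance. Each of them puts arrays of both groups on each side. The real difference then enters the spread and lowers the gene count. For 6 arrays of 1 comparison there are 10 splits, too few for a share under 0.05. The real 1 h split called 153 genes and the highest other 0, the real 4 h split 1693 and 1, and the mock split 1990 and 0. Gene lists passing numbered 2 at 1 h, with 7 in the highest other split, and 9 of the 10 splits gave at least 2; at 4 h they numbered 10, with 5 in the highest other. For the 146 genes shared by both times, 1 of 100 draws, the real one, gave as many and the highest other was 0. No other split of a single time called more than 1 gene, so the other draws had to share 0 and say no more than the splits of each time. The overlap itself is beyond that of independent lists by Fisher's exact test, one-sided: 130 shared rises against 7.22 (p = 9.26e-161) and 16 shared falls against 0.459 (p = 3.82e-24). That test takes genes as independent and the call lists as unrelated, though both times use the same estimate of each gene's spread.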

How the results depend on the processing

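The list tests without mock 4 h replicate 2, identical loci kept once, and centring combined with leaving out that array were chosen after the data were seen. No result passed in the opposite direction under any alternative. Of the counts under alternatives, 114 stayed within 1.5 times the value reported and 42 did not; of the values of named genes 8362 kept direction and side of the threshold, 274 lost it, 97 gained it and 149 changed sign without passing. For the medians of gene lists these numbers were 469, 28, 4 and 27.

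Stricter rules lowered counts by construction: a 2-fold minimum gave 55 genes at 1 h, 336 at 4 h and 132 for the difference of responses, and an adjusted p of 0.01 gave 96, 1008 and 117. With only the arrays of 1 time there were 251 genes at 1 h and 994 at 4 h, and with only the 6 mock arrays 1086 for mock. Array weights gave 378 at 1 h, 465 for the difference, 3120 for mock and 300 shared by both times. Centring without mock 4 h replicate 2 gave 263, 3219 for mock and 236 shared. For these settings the cause was not tested. The reported fit shares 1 spread across groups, while the median SD of a gene was 0.087 in mock and 0.105 in DEX at 1 h. At 4 h it was 0.165 in mock and 0.124 in DEX. For a typical gene the shared spread then lies above that of the 1 h arrays and below that of the 4 h arrays. The share that rose under array weights was 74.3% at 1 h, 57.3% at 4 h and 51.3% for mock.

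Leaving out single arrays or replicate numbers gave 51 to 263 genes at 1 h, 871 to 2022 at 4 h, 40 to 412 for the difference, 371 to 2439 for mock, and 50 to 235 shared. The lowest come from leaving out a replicate number, which leaves 8 arrays, and each highest from leaving out mock 4 h replicate 2. Lists were run without each replicate number and without mock 4 h replicate 2, which gave 7 to 9 at 4 h and 2 at 1 h; they were not run without the other single arrays.

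At 4 h an estimated correlation gave 2 lists, fry 8 of the 10 reported, and camera on ranks also 8, of which 7 are among the 10 and the clock list is not. The replicate block gave 153 genes at 1 h, 1697 at 4 h, 267 for the difference, 1907 for mock and 143 shared, and 2 and 11 lists. Arrays of the same number correlated in their deviations at 0.04, 0.06 and 0.19 at 1 h and -0.01, 0.19 and 0.10 at 4 h. Arrays of different numbers ran from -0.13 to 0.07 at 1 h and from -0.17 to 0.13 at 4 h. Not every array correlated best with its own number, so pairing by number is neither shown nor excluded. The numbers were not taken to pair the arrays in the reported fit. Among named genes the block ended the calls of CUC3 at 1 h and of ACS11 and TRY at 4 h.

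Of named calls, 12 of 37 at 1 h and 19 of 99 at 4 h ended without a single array, and 16 and 68 held in every alternative. The signal limits small effects: simulated changes of log2 0.5 were recovered for 46.3% of genes in the 1 h run and 40.3% in the 4 h run. Both runs gave each gene 1 SD for all groups, so they do not compare the times. The real 4 h comparison called 1693 loci, against 166 calls in its run, so its own recovery may differ.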

Other observations

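The tests in this part, of lists in mock plants and of anthocyanin, flavonol and histone genes, were chosen after the results were seen.

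Anthocyanin regulators rose with the structural genes at 4 h. Of 8 measured, 4 rose: AT1G56650 (PAP1), PAP2, TT8 and MYBL2, with a list median of 0.88 (camera adjusted p = 5.01e-06, and adjusted p = 0.0169 with an estimated correlation). MYBL2 is a repressor of the pathway and the others are activators. In the flavonol branch 3 of 4 genes rose (median 0.60, adjusted p = 0.0193; 0.101 with an estimated correlation). Both lists were drawn up because single anthocyanin genes led the rises, so they are no independent evidence. Of 18 histone genes 0 passed by limma at 4 h, 5 at an unadjusted p under 0.05; their median was -0.13 (-0.25 without mock 4 h replicate 2) and the list passed downward (adjusted p = 0.00714), which was lost at adjusted p = 0.525 with an estimated correlation.

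In mock plants 4 lists differed between 4 h and 1 h. All 10 clock genes changed, 7 higher and 3 lower at 4 h (median 0.71, mean 0.28, camera adjusted p = 0.0231). Of 21 mitotic genes 5 were higher (median 0.25, adjusted p = 2.60e-06), of 16 replication genes 5 lower (median -0.27, 0.000797) and of 12 expansins 4 lower (median -0.39, 0.000107). With an estimated correlation 0 of the 4 lists pass, the smallest adjusted p being 0.539 for expansins and mitotic genes. Time and array processing cannot be told apart in these values. The 4 lists were not run without mock 4 h replicate 2. That array deviated from the other mock 4 h arrays by a median of -0.33 for replication genes and -0.27 for expansins. The deviation was -0.22 for mitotic and -0.41 for clock genes.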
